A study of Homo sapiens with 8 samples.

How the data were processed

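The samples were islet-like cells made from H1 human embryonic stem cells of 4 genotypes (WT, ISL1 KO, PAX6 KO and PDX1 KO), transduced on day 11 with an ISL1 and blue fluorescent protein vector or with the fluorescent protein alone and harvested on day 18. Per the labels' protocols, RNA was extracted with a Zymo Quick-RNA kit, amplified with SMART-Seq v4 and made into libraries with a KAPA EvoPrep kit. This chemistry starts from full-length cDNA and marks neither strand nor single molecules, so counts from antisense or overlapping genes can mix, and amplified copies count as separate reads. The series describes 2 to 3 biological replicates per condition. GEO holds 8 samples, 1 per condition, and the replicates are columns of the deposited tables. In all 21 libraries were used, each read on 4 lanes. Another 12 columns, belonging to 3 libraries whose names match no sample's labels, were not used.

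The authors deposited gene-level estimated counts per library and lane, which hold fractions, per the values themselves and the submitters' processing notes, which name STAR and GRCh38. The counting program for these estimated counts is not given in the sources used here. A second deposited gene table holds counts that are whole numbers, and they differ from the estimated counts by at most 0.5, the rounding. The authors also deposited TPM values, scaled for transcript length and depth within each library and lane, per the file headers. Estimated transcript counts, as deposited by the authors, were used for ISL1 alone. A further table of counts without gene names was not used here.

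Estimated counts were summed over the 4 lanes of a library, where the lowest correlation between lanes was 0.990, and rounded to whole numbers before testing. The tables list 38592 genes by Ensembl identifier; 38568 were matched to a symbol in the GENCODE 29 annotation, the source of coordinates (GRCh38), and 24 were not. Library totals and genes detected per library are given in the report; CHGA or GCG was the gene with the most counts in each library and held 1.02% to 6.69% of them. TMM factors ran from 0.707 to 1.15. No interval or p-value separates reads from molecules, and intervals of shares cover counting error only.

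Genes were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter at its defaults (22184 genes kept), 1 model with a mean for each of the 8 groups, and the quasi-likelihood F test. The common dispersion was 0.114. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. SEs are those of the fitted log2 fold change. The comparisons were ISL1 OE against BFP within each genotype, each knockout against WT among BFP libraries, ISL1 KO ISL1 OE against WT BFP, and 5 differences between vector effects: ISL1 KO, PAX6 KO and PDX1 KO each minus WT, and PAX6 KO and PDX1 KO each minus ISL1 KO. A shared fit uses the spread of all 8 groups, so a library that stands apart in 1 group enters the spread used in every comparison. The part of the changes that the vector turned back was counted from calls in opposite directions, with exact binomial 95% intervals, and set beside 20 simulated sets, in which WT BFP and knockout BFP libraries were drawn at their fitted means and the knockout ISL1 OE libraries at the means of their BFP group, so that the chance values of the BFP libraries entered both comparisons.

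A set of 24 gene lists was fixed: islet hormones; beta, alpha, delta, gamma and epsilon, and enterochromaffin-like cells; secretory machinery; islet transcription factors; endocrine progenitors; pancreatic progenitors and duct; acinar cells; liver; intestine and stomach; neurons; mesenchyme; endothelium; pluripotency; proliferation; ER stress; interferon response; p53 response; hypoxia; exocytosis-coupled ion channels; and mitochondrially encoded genes. Several genes stand in more than 1 list, GCG and HHEX among them. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 24 lists. Where no value with an estimated correlation is given, the call of the list held with it too. In every called list the median, the mean and the test had the same sign.

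The genes named were the 3 altered genes, a panel of 16 islet genes (among them INS, GCG, SST, PPY, GHRL, IAPP, MAFA, NKX6-1, NKX2-2, NEUROD1, NEUROG3, CHGA, TPH1 and FEV; the others are not reported here), and in each comparison the 8 genes with the largest rise and the 8 with the largest fall among called genes with a symbol, a mean log2 CPM of at least 2 and groups that did not overlap; for differences between effects these were 5 and 5. Groups of 3 and 3 do not overlap by chance in 10% of genes. Up to 4 members of a described list with the smallest adjusted p were also named. Groups, comparisons, lists, this rule and the alternatives, except those said to be added, were fixed before the data were examined.

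The steps were tested on simulated counts for 21805 genes, with 100 genes changed 2-fold and 100 changed 4-fold. In the vector comparison of ISL1 KO 13% of the 2-fold and 79% of the 4-fold changes were called, with 7 false calls; in WT the shares were 4% and 64%, with 2 false calls, and in PAX6 KO 13% and 83%, with 3. Camera called a list of raised genes and not a list of unchanged genes.

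Libraries of different groups carry the same replicate numbers. Over 15688 genes, the deviations from the group means of the ISL1 OE and BFP libraries with the same number correlated with r = 0.427, 0.284 and 0.625 in ISL1 KO and 0.253, 0.512 and 0.546 in PAX6 KO, so numbers were taken to pair libraries in those genotypes, from the data and not from a stated shared day. Genes are not independent replicates.

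The alternatives tried were RLE factors or library size alone in place of TMM, no filter or a minimum of 10 counts in 2 libraries, DESeq2 1.42.0, limma-voom, limma on log2(TPM + 1), the table of rounded counts, a fit of only the compared groups, the replicate number as a block, a robust spread, an estimated correlation for lists, a stricter threshold for changes turned back, and each library left out in turn. After the data were seen, the lane set as a covariate, libraries of lanes 1 to 4 only, the replicate block within ISL1 KO and PAX6 KO only, and the reduced set without the 2 libraries that stand apart were added. Tables were handled with data.table (version 1.17.8), pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15, and plots were drawn with matplotlib 3.10.9.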

Results

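The study measured bulk RNA in islet-like cells made from H1, an established human embryonic stem cell line that was steered through pancreatic stages in culture. They were wild type (WT) or carried a knockout (KO) of ISL1, PAX6 or PDX1, each of which encodes a homeodomain transcription factor of islet cells. On day 11 the cells received either a vector carrying ISL1 together with blue fluorescent protein (labelled ISL1 OE) or the fluorescent protein alone (labelled BFP), and RNA was taken on day 18. The 21 libraries fell into 8 groups of biological replicates: 2 each for WT BFP, WT ISL1 OE and PDX1 KO ISL1 OE, and 3 each for ISL1 KO BFP, ISL1 KO ISL1 OE, PAX6 KO BFP, PAX6 KO ISL1 OE and PDX1 KO BFP. In WT BFP replicate 3 the total gene count was the lowest and in ISL1 KO BFP replicate 3 the highest (40959445 and 66818593 counts), and 24721 to 27304 genes were detected per library. Levels are normalised read counts (CPM) after TMM scaling, given as mean ± SD over n libraries, and log2 fold changes are given ± SE. All adjusted p-values for genes come from edgeR's quasi-likelihood test unless another tool is named.

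The altered genes were examined first. ISL1 (ENSG00000016082, GRCh38 chromosome 5, 51383391 to 51394738, plus strand) had 384 ± 141 CPM in WT BFP (n = 2) and 67.5 ± 3.88 CPM in ISL1 KO BFP (n = 3). The log2 fold change was −2.51 ± 0.38 with adjusted p = 0.000831. ISL1 RNA was not detectably higher in libraries labelled ISL1 OE than in the BFP libraries of the same genotype. Its level was 320 ± 9.07 CPM in WT ISL1 OE (n = 2), 72.9 ± 11.2 in ISL1 KO ISL1 OE (n = 3), 194 ± 107 in PAX6 KO ISL1 OE (n = 3) against 176 ± 46.6 in PAX6 KO BFP (n = 3), and 203 ± 107 in PDX1 KO ISL1 OE (n = 2) against 140 ± 17.1 in PDX1 KO BFP (n = 3). Its log2 fold changes were −0.27 ± 0.42 in WT, 0.11 ± 0.34 in ISL1 KO, 0.15 ± 0.34 in PAX6 KO and 0.54 ± 0.38 in PDX1 KO, with adjusted p = 1, 1, 0.867 and 0.341. The upper 95% bounds were 0.56, 0.78, 0.82 and 1.28. The vector label is therefore not checked by the RNA of its own gene, and the libraries are called labelled ISL1 OE throughout. PAX6 (ENSG00000007372, chromosome 11, 31784779 to 31818062, minus strand) had 132 ± 30.6 CPM in PAX6 KO BFP and 189 ± 64.9 in WT BFP (−0.52 ± 0.43, adjusted p = 0.569). PDX1 (ENSG00000139515, chromosome 13, 27920020 to 27926231, plus strand) had 101 ± 6.44 CPM in PDX1 KO BFP and 84.5 ± 14.9 in WT BFP (0.25 ± 0.23, adjusted p = 0.572). A knockout made by a small edit can leave RNA in place, so the level of these transcripts does not check the PAX6 KO and PDX1 KO labels.

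**Figure D1:**
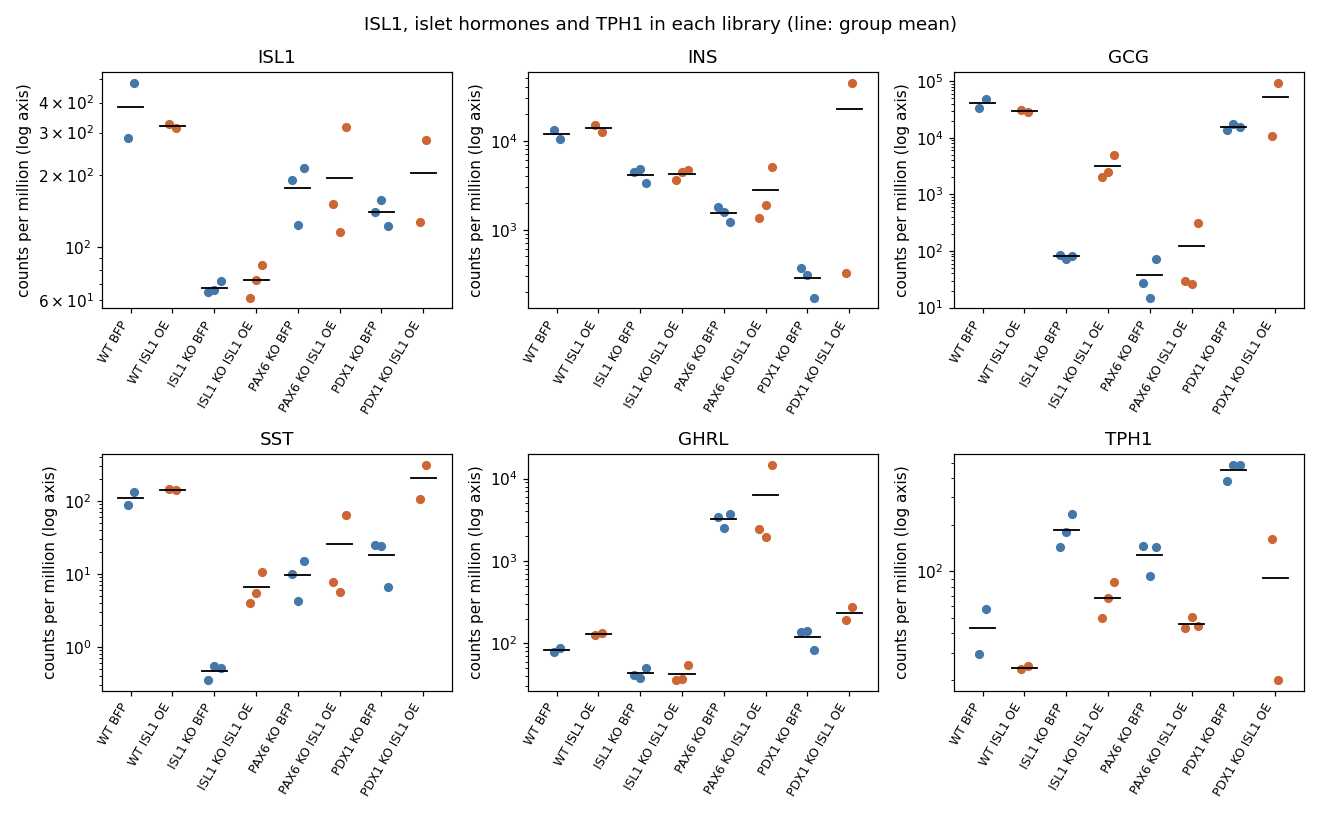
Level of ISL1 and of the hormone and serotonin pathway genes INS, GCG, SST, GHRL and TPH1 in each of the 21 libraries, in TMM-normalised CPM on a logarithmic axis, by genotype and vector; each point is a library and each line a group mean. ISL1 does not separate the ISL1 OE from the BFP libraries within a genotype, while GCG is 80.4 CPM on average in ISL1 KO BFP and 3216 CPM in ISL1 KO ISL1 OE.

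A pair of libraries stood apart from their groups. Within groups the correlation of log2 CPM across genes was 0.982 or higher, except for PAX6 KO ISL1 OE, where the lowest pair reached 0.927, and for the 2 libraries of PDX1 KO ISL1 OE, which reached 0.900. On the fourth principal component, with 8.12% of the variance, PAX6 KO ISL1 OE replicate 3 lay at −53.9 and the library labelled PDX1 KO ISL1 OE replicate 4 at −40.9. The latter held 44875 CPM of INS and 94730 CPM of GCG, while its partner, replicate 2, held 324 and 10836 CPM. It also had the lowest TMM factor, 0.707. Counts of called genes are given with all libraries and, as an alternative chosen after the data were seen, with both of these libraries left out, which is called the reduced set.

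**Figure D2:**
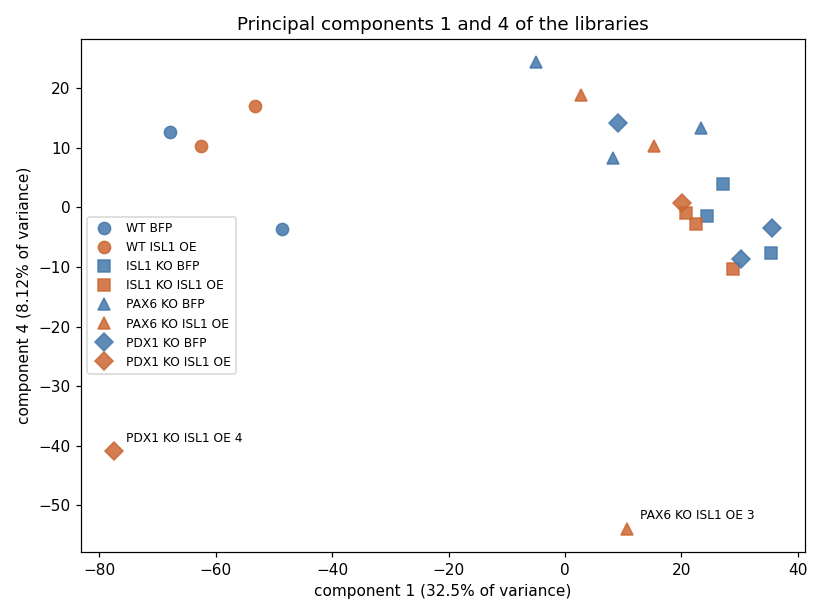
Principal component 1 (32.5% of the variance) against principal component 4 (8.12%) of log2 CPM over the 2000 most variable genes, with marker shape for genotype and colour for vector (blue BFP, orange ISL1 OE); each point is a library. PAX6 KO ISL1 OE replicate 3 and the library labelled PDX1 KO ISL1 OE replicate 4 lie at −53.9 and −40.9 on component 4.

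The comparison of ISL1 KO BFP (n = 3) with WT BFP (n = 2) shows the state on which the ISL1 vector acted. Hormone genes of several islet cell types fell in ISL1 KO. GCG, the glucagon gene of alpha cells (ENSG00000115263, chromosome 2, 162142873 to 162152404, minus strand), had 80.4 ± 7.23 CPM against 41066 ± 10115 in WT, a log2 fold change of −9.0 ± 1.16 with adjusted p = 0.000203. SST, the somatostatin gene of delta cells (ENSG00000157005, chromosome 3, 187668906 to 187670399, minus strand), fell by 7.86 ± 1.03 on the log2 scale (adjusted p = 0.000246), from 110 ± 31.5 to 0.473 ± 0.102 CPM. INS, the insulin gene (ENSG00000254647, chromosome 11, 2159779 to 2161341, minus strand), had 4164 ± 754 CPM against 11864 ± 2011. With all libraries this difference did not pass (−1.51 ± 0.94, adjusted p = 0.398). In the reduced set, which drops no library of these groups, all 7 islet hormone genes tested, INS among them, were called lower. Genes of serotonin-producing enterochromaffin-like cells rose, among them TPH1, the first enzyme of serotonin synthesis (2.09 ± 0.57, adjusted p = 0.0361), the decarboxylase gene DDC (1.17 ± 0.20, adjusted p = 0.00197) and CBLN1, which encodes a secreted synapse organiser (2.53 ± 0.34, adjusted p = 0.000333).

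By list, 7 of the 12 delta cell genes tested fell in ISL1 KO and none rose, and 9 fell when adjusted over the list alone (camera adjusted p = 4.22e-11). HHEX, a transcription factor of delta cells, fell by 2.42 ± 0.31 on the log2 scale, and the fatty acid receptor gene FFAR4 fell by 3.78 ± 0.61. Of the 20 alpha cell genes 10 fell and none rose, with 11 lower and 1 higher when adjusted over the list alone (camera adjusted p = 4.22e-11). They include GPR119, a lipid receptor (−4.40 ± 0.28). The islet hormone list had 5 of 7 lower under both adjustments (camera adjusted p = 4.22e-11), and the gamma and epsilon cell list 5 of 11 lower, 7 when adjusted over the list alone (camera adjusted p = 1.36e-07). Of 12 enterochromaffin-like genes 6 rose and none fell, and 8 rose when adjusted over the list alone (camera adjusted p = 8.2e-07). The beta cell list was mixed, with 3 higher and 8 lower of 28 (4 and 8 adjusted over the list alone). Its camera adjusted p was 0.00377, or adjusted p = 0.189 with an estimated correlation. The zinc transporter gene SLC30A8 (−2.80 ± 0.27) and G6PC2, an islet glucose-6-phosphatase gene (−6.23 ± 0.91), fell, while the beta cell transcription factor NKX6-1 rose (1.83 ± 0.40). Genes named for other cell types and for stress fell too: 7 of 17 liver genes including transferrin, TF (−5.13 ± 0.31), 6 of 13 acinar genes, 6 of 14 p53 response genes including CDKN1A (−1.91 ± 0.27), and 3 of 16 ER stress genes including the chaperone gene HSPA5 (−0.74 ± 0.15). Adjusted over the list alone, these counts were 12, 7, 7 and 3, and the camera adjusted p-values were 1.68e-12, 1.96e-05, 2.74e-06 and 0.000298. The interferon response list had 4 higher and 1 lower of 18, 5 and 3 when adjusted over the list alone (camera adjusted p = 0.0333, or adjusted p = 0.15 with an estimated correlation). None of 20 proliferation genes passed, 2 rose when adjusted over the list alone, and the camera adjusted p of 3.86e-05 became adjusted p = 0.338 with an estimated correlation.

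In all, 455 genes were higher and 994 lower in ISL1 KO than in WT at an adjusted p under 0.05. The largest rises among the genes named by rule were in PROKR1, a prokineticin receptor gene (3.88 ± 0.92), B3GAT1, a glucuronyltransferase gene of neural glycans (3.67 ± 0.37), and DLX5, a homeobox gene (3.47 ± 0.80). The largest falls after GCG and SST included TSPYL5 (−7.64 ± 0.82), ZNF585A (−7.15 ± 0.64) and PYY, the peptide YY gene (−6.79 ± 1.03). Library size alone as scaling moved the higher share from 31.4% to 43.2%, and in the reduced set 3060 genes were higher and 3481 lower, with all 1449 calls among them. The 1449 calls became 450 and 472 without WT BFP replicates 1 and 3, and 725, 935 and 601 without ISL1 KO BFP replicates 1, 2 and 3. Of 78 called genes named by rule, 36 (GCG, SST, HHEX and CBLN1 among them) kept the call each time. TPH1 lost it each time, with adjusted p up to 0.296, and also with the replicate block within ISL1 KO and within PAX6 KO (adjusted p = 0.0664), and NKX6-1 without WT BFP replicate 1 (adjusted p = 0.161).

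In PAX6 KO BFP (n = 3) against WT BFP (n = 2), glucagon RNA fell while ghrelin RNA rose. GCG had 38.2 ± 30 CPM against 41066 ± 10115 (−10.07 ± 1.21, adjusted p = 0.000153). GHRL, the ghrelin gene of epsilon cells, had 3207 ± 612 CPM against 83.1 ± 7.78 (5.27 ± 0.74, adjusted p = 0.000615). NEUROG3, the transcription factor of endocrine progenitors, rose from 135 ± 39.3 to 928 ± 226 CPM (2.78 ± 0.37, adjusted p = 0.000384). SST fell by 3.48 ± 0.85 (adjusted p = 0.0217), and INS, at 1545 ± 296 against 11864 ± 2011 CPM, did not pass (−2.94 ± 0.96, adjusted p = 0.0782).

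Of 28 beta cell genes 12 fell and 1 rose in PAX6 KO, with 15 and 5 when adjusted over the list alone (camera adjusted p = 2.4e-10). SLC30A8 (−3.11 ± 0.27), the redox enzyme gene ERO1B (−3.26 ± 0.29) and the glucose transporter gene SLC2A2 (−2.56 ± 0.50) were among those that fell. Of 20 alpha cell genes 7 fell and none rose, 8 and 1 when adjusted over the list alone (camera adjusted p = 7.31e-07). In the delta cell list 4 of 12 fell and 1, FFAR4 (2.09 ± 0.59), rose, the same counts as over the list alone (camera adjusted p = 0.0108). Of 16 endocrine progenitor genes 5 rose and none fell, 7 when adjusted over the list alone (camera adjusted p = 0.000126). Besides NEUROG3 they were SOX4 (0.79 ± 0.18), NHLH1 (1.82 ± 0.48), HES6 (1.22 ± 0.33) and PAX4 (1.05 ± 0.30). The islet hormone list had 1 higher and 5 lower of 7, 1 and 6 over the list alone (camera adjusted p = 7.97e-06, or adjusted p = 0.14 with an estimated correlation). The gamma and epsilon cell list went both ways, with 3 of 11 higher and 5 lower (camera adjusted p = 0.103); MBOAT4, the acyltransferase that activates ghrelin, rose by 1.69 ± 0.36. Among enterochromaffin-like genes CBLN1 (1.37 ± 0.32) and the monoamine transporter gene SLC18A1 (1.86 ± 0.50) rose and the monoamine oxidase gene MAOB (−1.40 ± 0.40) fell. Over the list alone 3 rose and 1 fell, and the camera adjusted p of 0.0267 became adjusted p = 0.277 with an estimated correlation. Of 17 liver genes 11 fell, 13 over the list alone (camera adjusted p = 3.8e-11). ER stress genes (5 of 16), interferon response genes (4 of 18) and p53 response genes (3 of 14) fell, with camera adjusted p = 0.000265, 0.000553 and 0.000265; over the list alone the counts were 6, 4 and 5. For the neuron list (4 of 21 higher, among them POU4F1, 2.92 ± 0.63; camera adjusted p = 0.014) and the endothelium list (2 of 7 lower, among them KDR, −3.07 ± 0.58; camera adjusted p = 0.00651) the value was adjusted p = 0.14 with an estimated correlation; over the list alone they had 6 higher and 2 lower, and 4 lower and 1 higher. Islet transcription factors (3 of 30 higher, 2 lower), acinar genes (2 of 13 lower) and mitochondrially encoded genes (0 of 13) had camera adjusted p = 0.0305, 0.0305 and 0.0344, or adjusted p = 0.472, 0.143 and 0.631 with an estimated correlation. Over the list alone 6 islet transcription factors rose and 2 fell, 2 acinar genes fell and 0 mitochondrially encoded genes passed.

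PAX6 KO had 534 genes higher and 942 lower than WT. The strongest rises by rule included COL12A1, a collagen gene (3.81 ± 0.73), CRH, the corticotropin-releasing hormone gene (3.59 ± 0.90), and the HMG-box gene SOX21 (3.23 ± 0.68). The strongest falls included FFAR1, a fatty acid receptor gene (−8.47 ± 0.85), PYY (−7.78 ± 1.09), CAT, which encodes catalase (−6.39 ± 0.38), and the cholecystokinin gene CCK (−6.10 ± 1.02). Library size alone moved the higher share from 36.2% to 55.6%, and in the reduced set 3188 genes were higher and 3425 lower, all 1476 calls included. The calls numbered 277 and 288 without WT BFP replicates 1 and 3 and 538 and 579 without PAX6 KO BFP replicates 1 and 3. Without each library in turn, 23 of 75 called genes named by rule (GCG, GHRL, NEUROG3, CAT and PYY among them) kept the call, and SST lost it each time, with adjusted p up to 0.14. SLC18A1 (adjusted p = 0.0649) and NHLH1 (adjusted p = 0.0543) lost the call with the replicate block within ISL1 KO and within PAX6 KO.

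PDX1 KO BFP (n = 3) against WT BFP (n = 2) combined a loss of insulin RNA with higher serotonin pathway genes. INS had 286 ± 102 CPM against 11864 ± 2011 (−5.38 ± 1.05, adjusted p = 0.00354). IAPP, the amylin gene of beta cells, fell by 4.38 ± 0.94 (adjusted p = 0.00604). TPH1 rose from 43.3 ± 19.5 to 449 ± 58.3 CPM (3.37 ± 0.61, adjusted p = 0.00208), and FEV, a transcription factor of serotonergic cells, rose from 379 ± 44.4 to 1411 ± 173 CPM (1.90 ± 0.44, adjusted p = 0.00988). GCG, at 15617 ± 2047 CPM (−1.39 ± 0.89, adjusted p = 0.378), and SST (−2.58 ± 0.83, adjusted p = 0.0539) did not pass. ISL1 RNA itself was lower than in WT (−1.46 ± 0.38, adjusted p = 0.0186).

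Of 12 enterochromaffin-like genes 7 rose and 1 fell in PDX1 KO, 8 and 1 when adjusted over the list alone (camera adjusted p = 2.61e-07). Examples are CBLN1 (2.92 ± 0.35), SLC18A1 (2.98 ± 0.53) and DDC (1.42 ± 0.20), and MAOB fell (−1.66 ± 0.41). Of 28 beta cell genes 13 fell and 3 rose, 16 and 5 over the list alone (camera adjusted p = 3.53e-05, or adjusted p = 0.072 with an estimated correlation); those that rose were NKX6-1 (2.36 ± 0.41), MNX1 (2.22 ± 0.37) and the prohormone convertase gene PCSK1 (1.95 ± 0.56). The delta cell genes HHEX (−2.29 ± 0.31), FRZB, a secreted Wnt antagonist (−2.29 ± 0.43), and RBP4 (−3.69 ± 0.70) fell among 12, 4 over the list alone (camera adjusted p = 0.000316). Of 30 islet transcription factors 10 rose and 3 fell, 12 and 4 over the list alone (camera adjusted p = 0.00242, or adjusted p = 0.297 with an estimated correlation). Secretory machinery genes had 4 higher and 2 lower of 27, 10 and 3 over the list alone, with SYT13, a synaptotagmin gene, at 2.26 ± 0.23 (camera adjusted p = 0.00141, or adjusted p = 0.339 with an estimated correlation). Acinar (4 of 13) and ER stress (6 of 16) genes fell, 7 and 6 over the list alone, with camera adjusted p = 0.000478 and 0.000651. The lists of the liver (13 of 17 lower, 1 higher), of pancreatic progenitor and duct (4 of 17 lower) and of proliferation (6 of 20 lower) had camera adjusted p = 6.71e-12, 0.000196 and 1.45e-06, or adjusted p = 0.0615, 0.0728 and 0.237 with an estimated correlation. Over the list alone they had 14, 9 and 14 lower. Islet hormones (2 of 7 lower), alpha cell (6 of 20 lower, 1 higher), gamma and epsilon cell (4 of 11 lower, 1 higher), endothelium (3 of 7 lower), pluripotency (1 of 8 lower) and p53 response genes (4 of 14 lower) were called by camera with adjusted p = 0.00376, 0.00471, 0.00378, 0.0027, 0.013 and 0.00242. Over the list alone 4, 8, 5, 4, 5 and 6 were lower. With an estimated correlation these were adjusted p = 0.297, 0.204, 0.151, 0.111, 0.211 and 0.101.

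PDX1 KO had 1011 genes higher and 1518 lower than WT. The largest rises were in PROKR1 (5.17 ± 0.98), the potassium channel partner KCNIP1 (4.28 ± 0.52) and ARPP21, a cAMP-regulated phosphoprotein gene (4.05 ± 0.50), and the largest falls in GAST, the gastrin gene (−5.39 ± 1.0), and the calcium-sensing receptor gene CASR (−5.16 ± 0.63). With the reduced set 3627 genes were higher and 4028 lower, all 2529 calls included. The calls numbered 771 and 999 without WT BFP replicates 1 and 3 and 1468 and 1410 without PDX1 KO BFP replicates 2 and 3. The call was kept without each library by 50 of 96 called genes named by rule (INS, IAPP, TPH1 and NKX6-1 among them), and FEV lost it without either WT library, with adjusted p up to 0.137. FRZB had −1.42 (adjusted p = 0.118) without WT BFP replicate 1. No label gives more than 1 clone per knockout, so each difference from WT holds between these cultures.

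The effect of the ISL1 vector in its own knockout was read from ISL1 KO ISL1 OE (n = 3) against ISL1 KO BFP (n = 3). GCG had 3216 ± 1617 CPM against 80.4 ± 7.23, a rise of 5.32 ± 0.97 on the log2 scale with adjusted p = 0.018. HHEX (2.64 ± 0.29, adjusted p = 0.000406) and FRZB, from 22.6 ± 3.86 to 176 ± 18.7 CPM (2.96 ± 0.42, adjusted p = 0.00343), rose. The largest rises by rule were in PRDM14, a regulator of pluripotent cells (4.62 ± 0.64, adjusted p = 0.00314), RIPPLY3, a transcriptional corepressor gene (4.22 ± 0.42, adjusted p = 9.61e-05), VSIG1, a junction protein gene of stomach epithelium (3.94 ± 0.49, adjusted p = 0.000998), and the NADPH oxidase gene NOX4 (3.75 ± 0.32, adjusted p = 3.62e-05). CBLN1 fell from 123.8 ± 36.2 to 37.7 ± 7.14 CPM (−1.72 ± 0.28, adjusted p = 0.00885). INS had a log2 fold change of 0.03 ± 0.85 (adjusted p = 1). SST, at 6.72 ± 3.58 against 0.473 ± 0.102 CPM, did not pass (3.82 ± 0.87, adjusted p = 0.0741).

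Of 12 delta cell genes 2 rose and none fell, and 5 rose when adjusted over the list alone (camera adjusted p = 7.35e-14). Of 12 enterochromaffin-like genes 3 fell and none rose, and 8 fell over the list alone (camera adjusted p = 1.42e-14). The 3 were CBLN1, DDC (−1.07 ± 0.18) and MME, which encodes the peptidase neprilysin (−1.98 ± 0.41). TPH1 (−1.44 ± 0.48, adjusted p = 0.288) and FEV (−1.12 ± 0.37, adjusted p = 0.293) did not pass over all genes. The pluripotency list had 2 of 8 higher, PRDM14 and LIN28A (1.32 ± 0.26), and 3 over the list alone (camera adjusted p = 2.49e-09). GCG alone of 7 islet hormones rose, 5 over the list alone (camera adjusted p = 4.12e-08, or adjusted p = 0.117 with an estimated correlation). In the secretory machinery list SYT13 alone of 27 fell (−1.36 ± 0.19), with 1 higher and 3 lower over the list alone (camera adjusted p = 3.62e-06, or adjusted p = 0.411 with an estimated correlation). The intestine and stomach list had 0 of 13 passing and 3 higher over the list alone (camera adjusted p = 0.000442, or adjusted p = 0.0521 with an estimated correlation). Proliferation (higher, 0 of 20), exocytosis-coupled ion channels (lower, 0 of 18), pancreatic progenitor and duct (higher, 1 of 17) and mesenchyme (lower, 0 of 14) were called by camera with adjusted p = 7.28e-05, 0.0111, 0.0339 and 0.0494, or adjusted p = 0.442, 0.426, 0.423 and 0.5 with an estimated correlation.

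The vector comparison in ISL1 KO called 54 genes higher and 40 lower, or 50 and 23 with library size alone as scaling, which moved the higher share from 57.4% to 68.5%. Neither library left out of the reduced set is an ISL1 KO library, but the spread shared by all groups was smaller there, and 540 genes were higher and 821 lower, with all 94 among them. GCG then had adjusted p = 1.18e-05, SST 0.000884, TPH1 0.00229 and FEV 0.00156. With the replicate number as a block within ISL1 KO and within PAX6 KO, SST was called (3.73 ± 0.63, adjusted p = 0.0239), while SLC4A4, ARPP21, MME, PPP1R17, NETO1, NEFL, LIN28A and MEIS2 lost the call, with adjusted p = 0.0611 to 0.0939. Among libraries of lanes 1 to 4 only, 4 genes were called, and with only the compared groups in the fit 1461. The 94 calls became 46, 33 and 20 without ISL1 KO BFP replicates 1, 2 and 3, and 39, 34 and 54 without ISL1 KO ISL1 OE replicates 1, 2 and 3. PRDM14, RIPPLY3, VSIG1, NOX4, FRZB and HHEX were among the 9 of 26 called genes named by rule that kept the call each time. GCG lost it without each ISL1 KO BFP library and without ISL1 KO ISL1 OE replicate 3, with adjusted p up to 0.142. CBLN1 lost it without ISL1 KO BFP replicate 3 and ISL1 KO ISL1 OE replicates 1 and 2, with adjusted p up to 0.0803.

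In PAX6 KO ISL1 OE (n = 3) against PAX6 KO BFP (n = 3), the beta cell transcription factor NKX6-1 fell from 114.7 ± 30.5 to 31.3 ± 3.89 CPM (−1.87 ± 0.35, adjusted p = 0.0248). HHEX rose from 6.82 ± 1.34 to 29.8 ± 10.3 CPM (2.13 ± 0.29, adjusted p = 0.00342), and NOX4 (2.16 ± 0.30, adjusted p = 0.0039) and RARRES2, the chemerin gene (2.13 ± 0.33, adjusted p = 0.0072), rose. CBLN1 fell from 55.5 ± 12 to 14.7 ± 2.33 CPM (−1.92 ± 0.29, adjusted p = 0.00496) and DDC fell by 1.37 ± 0.18 (adjusted p = 0.00253). GCG (1.66 ± 0.83, adjusted p = 0.484) and INS (0.84 ± 0.86, adjusted p = 0.686) did not pass. GCG had a log2 fold change of −0.43 ± 0.46 in the reduced set.

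Of 12 enterochromaffin-like genes 3 fell and none rose, and 10 fell when adjusted over the list alone (camera adjusted p = 1.22e-16); in the reduced set 9 fell over all genes, TPH1 among them (−1.42 ± 0.29). Of 12 delta cell genes HHEX and FRZB (1.93 ± 0.40) rose, 3 over the list alone (camera adjusted p = 0.00906, or adjusted p = 0.0889 with an estimated correlation). Beta cell genes had 1 of 28 lower, 8 over the list alone (camera adjusted p = 0.000434, or adjusted p = 0.259 with an estimated correlation). Secretory machinery genes had SYT13 alone of 27 lower (−1.21 ± 0.19), 8 over the list alone (camera adjusted p = 8.62e-07, or adjusted p = 0.276 with an estimated correlation). TFF2, a trefoil factor gene of stomach mucosa (1.84 ± 0.38), rose in the intestine and stomach list, where 5 rose and 1 fell over the list alone (camera adjusted p = 0.0347, or adjusted p = 0.276 with an estimated correlation). Islet transcription factors (1 of 30 higher, 1 lower), endocrine progenitor genes (1 of 16 lower, NEUROD4, −1.76 ± 0.35) and ion channels (0 of 18, 4 lower over the list alone) were called lower by camera with adjusted p = 0.00218, 0.0105 and 4.1e-05. Proliferation, islet hormone and mitochondrially encoded genes, with no member passing, were called higher with adjusted p = 0.000418, 0.0202 and 0.0236. None of these 6 held with an estimated correlation (adjusted p = 0.414, 0.276, 0.259, 0.439, 0.443 and 0.539), and in the reduced set islet hormone and mitochondrially encoded genes turned to lower, with adjusted p = 0.921 and 0.573.

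The vector comparison in PAX6 KO called 45 genes higher and 47 lower. Other genes named by rule were IGFBP7, an insulin-like growth factor binding protein gene (2.46 ± 0.45), VSIG1 (2.39 ± 0.45) and RIPPLY3 (1.87 ± 0.37) among those that rose, and MME (−2.24 ± 0.41), ARPP21 (−2.15 ± 0.39) and BRINP3 (−2.25 ± 0.46) among those that fell. With the replicate block the calls were 35 (13 higher, 22 lower), of which 33 were shared. NKX6-1, IGFBP7, VSIG1, FRZB, RIPPLY3, PLA2G10, PIRT, BRINP3, MME, ARPP21 and TFF2 then had adjusted p = 0.0557 to 0.123. In the reduced set, which lacks PAX6 KO ISL1 OE replicate 3, IGFBP7 had 1.74 ± 0.26, RIPPLY3 1.14 ± 0.19 and RARRES2 1.41 ± 0.16. There 422 genes were higher and 962 lower, all 92 among them, and with library size alone the calls were 29 and 26. With only the compared groups in the fit edgeR called 0 genes, with 1351 at an unadjusted p under 0.05, and among libraries of lanes 1 to 4 it called 0, with 1002; over all libraries DESeq2 called 499 and limma-voom 88. The calls numbered 17 and 20 without PAX6 KO BFP replicates 1 and 3. They numbered 39 and 63 without PAX6 KO ISL1 OE replicates 1 and 3, and the 63 held 38 of the 92. NKX6-1 lost the call each time, with adjusted p up to 0.142. NOX4, HHEX, CBLN1, KLHDC8A and DDC, 5 of 20 called genes named by rule, kept the call without each library.

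In WT the vector comparison (n = 2 and 2) called 8 genes higher and none lower. VSIG1 rose from 1.32 ± 0.123 to 28.6 ± 7.7 CPM (4.43 ± 0.62, adjusted p = 0.00929). The vitamin B12 binding protein gene TCN1 (2.82 ± 0.40, adjusted p = 0.00929), RARRES2 (2.74 ± 0.42, adjusted p = 0.0192), NOX4 (2.72 ± 0.37, adjusted p = 0.00929) and NMNAT3, an NAD synthesis gene (2.06 ± 0.26, adjusted p = 0.00873), also rose. INS (0.23 ± 1.04), GCG (−0.45 ± 0.99) and SST (0.37 ± 0.90) had adjusted p = 1. None of 12 delta cell genes passed over all genes; HHEX (1.81 ± 0.35, adjusted p = 0.107) and FRZB (1.49 ± 0.49, adjusted p = 0.78) were the 2 that passed over the list alone, and camera called the list higher with adjusted p = 8.45e-05. The hypoxia list was called lower, with no member passing under either adjustment (camera adjusted p = 0.0002). Of 13 intestine and stomach genes none passed over all genes and 4 rose over the list alone, led by TFF2 (2.61 ± 0.50), with camera adjusted p = 0.000249. The enterochromaffin-like list had 0 of 12 passing and 2 lower over the list alone, led by DDC (−0.92 ± 0.21; camera adjusted p = 0.000249, or adjusted p = 0.131 with an estimated correlation). Liver and ER stress genes were called lower with adjusted p = 2.61e-06 and 0.00803, or adjusted p = 0.226 and 0.127 with an estimated correlation, with no member passing over all genes and 1, the liver gene TF, lower over the list alone. Neuron, mesenchyme, pluripotency, proliferation and ion channel genes, with 1, 0, 1, 0 and 0 members higher over the list alone and none over all genes, were called higher with adjusted p = 0.0278, 0.0316, 0.0276, 0.0276 and 0.0276. With an estimated correlation these were adjusted p = 0.298, 0.64, 0.337, 0.64 and 0.549.

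At an unadjusted p under 0.05, 844 genes differed in WT. The 8 calls became 0 without WT BFP replicate 1, without WT BFP replicate 3 and without WT ISL1 OE replicate 2, and 5 without WT ISL1 OE replicate 1, each time leaving a lone library that is assumed to vary like the other groups. The reduced set gave 183 genes higher and 205 lower, all 8 included. With only the compared groups in the fit 281 genes were called, and among libraries of lanes 1 to 4 edgeR called 0, with 648 at an unadjusted p under 0.05; over all libraries DESeq2 called 63 and limma-voom 7. VSIG1 lost the call with the replicate block within ISL1 KO and within PAX6 KO (adjusted p = 0.0616).

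In PDX1 KO the vector comparison rested on 2 libraries labelled ISL1 OE that differed from each other, against 3 BFP libraries. AGR2, a disulfide isomerase gene of mucus-secreting cells, rose from 38.8 ± 1.99 to 818 ± 111.1 CPM (4.40 ± 0.63, adjusted p = 0.000546). FRZB (4.05 ± 0.46, adjusted p = 8.41e-05) and HHEX (2.62 ± 0.31, adjusted p = 0.000119) rose. NKX6-1 fell from 295 ± 30.8 to 43.3 ± 32.9 CPM (−2.77 ± 0.42, adjusted p = 0.000851), and CBLN1 fell by 2.60 ± 0.34 (adjusted p = 0.000286). INS was called higher (6.30 ± 1.09, adjusted p = 0.00202), but this direction came from the library labelled PDX1 KO ISL1 OE replicate 4. INS in the reduced set had a log2 fold change of 0.20 ± 0.33, AGR2 4.28 ± 0.65, NKX6-1 −2.12 ± 0.35 and SST 2.56 ± 0.57.

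Of 12 enterochromaffin-like genes 8 fell and none rose, 9 and 1 when adjusted over the list alone (camera adjusted p = 3.82e-08). Of 12 delta cell genes 4 rose under both adjustments (camera adjusted p = 0.00224), and of 13 acinar genes 7 rose under both, among them PRSS1, a trypsinogen gene (3.25 ± 0.51; camera adjusted p = 6.33e-06). The counts for these lists in the reduced set were 10 lower and 2 higher, 4 higher, and 5 higher and 1 lower. Liver (11 of 17, 14 over the list alone), pancreatic progenitor and duct (7 of 17, 8), intestine and stomach (7 of 13, 8), proliferation (9 of 20, 11) and islet hormone genes (4 of 7, 4) rose with camera adjusted p = 1.03e-08, 0.000117, 0.000756, 5.7e-06 and 0.00353. With an estimated correlation these were adjusted p = 0.133, 0.0746, 0.0655, 0.367 and 0.367, and in the reduced set 8, 9, 8, 2 and 1 rose. Secretory machinery genes (10 of 27 lower, 18 over the list alone), islet transcription factors (8 of 30 lower, 11 over the list alone) and ion channels (4 of 18 lower, 8 over the list alone) had camera adjusted p = 6.94e-07, 0.00016 and 0.00477, or adjusted p = 0.273, 0.337 and 0.367 with an estimated correlation. None of 13 mitochondrially encoded genes passed and 9 rose over the list alone (camera adjusted p = 0.00412, or adjusted p = 0.475 with an estimated correlation); in the reduced set the list turned to lower, with adjusted p = 0.328.

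With all libraries 2016 genes were called higher and 1184 lower in PDX1 KO, a count that leaned on the library labelled PDX1 KO ISL1 OE replicate 4: GAST (6.47 ± 1.05), IL32 (5.06 ± 0.68) and RBP4 (4.44 ± 0.72) led the rises, and in the reduced set GAST had 0.99 ± 0.36 (adjusted p = 0.0903), IL32 2.35 ± 0.38 and RBP4 1.86 ± 0.37. The 3200 calls became 718 without replicate 4, 10860 without replicate 2, and 1834, 1587 and 1281 without PDX1 KO BFP replicates 1, 2 and 3. In the reduced set 1587 genes were higher and 983 lower, 1311 shared with the 3200, from a lone ISL1 OE library, and with library size alone as scaling 1189 were higher and 921 lower. With only the compared groups in the fit edgeR called 0 genes, with 3016 at an unadjusted p under 0.05, and among libraries of lanes 1 to 4 it called 189. Over all libraries DESeq2 called 5038, and limma-voom called 1050 higher and 1479 lower. PRDM14, PHLDA3 and LDHA, called higher with all libraries, turned to lower when 1 of the 2 was left out: PRDM14 without replicate 2 (−0.39), PHLDA3 and LDHA without replicate 4 (−0.048 and −0.47). LDHA also lost the call with the replicate block within ISL1 KO and within PAX6 KO (adjusted p = 0.0797).

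The same genes recurred in the vector comparisons of different genotypes. Of 22163 genes tested, 15 were called higher and 24 lower in both ISL1 KO and PAX6 KO, where independent lists would share 0.0985 and 0.0848, and none was called in opposite directions; these comparisons share no library. With the replicate block within both genotypes 7 were called higher and 12 lower in both, where independent lists would share 0.0264 and 0.0327, and 17 of these 19 were among the 39. The genes higher in both with and without the block include NOX4, HHEX, RARRES2 and NMNAT3, and those lower in both include CBLN1, DDC, SYT13 and NXPH4. With the block RIPPLY3, VSIG1, FRZB and B3GAT1 lost the call in PAX6 KO (adjusted p = 0.0597 to 0.123), and MME and ARPP21 lost it in both genotypes. Of the 39 genes called without the block, 35 had the same sign in WT. All 39 had the same sign in each of the 2 libraries labelled PDX1 KO ISL1 OE against the PDX1 KO BFP mean. For replicate 4, whose cells may be of another line, this does not speak for a vector effect. In PDX1 KO BFP, CBLN1, DDC and HHEX differed from WT BFP against the vector's direction. Cells like WT would give these the same signs with no vector. The rest were not counted. The median absolute log2 fold change of the 39 genes was 1.54 in ISL1 KO, 1.73 in PAX6 KO and 0.73 in WT. The genes were chosen by their calls in ISL1 KO and PAX6 KO, which favours large values there. These medians therefore do not show a weaker effect in WT. Across all genes the log2 fold changes of ISL1 KO and PAX6 KO correlated with r = 0.317; genes are not independent replicates. Of the 8 genes called in WT, 4 were called higher in ISL1 KO, 6 in PAX6 KO and 7 in PDX1 KO. The library kit does not mark strand, so the values of antisense genes among the 39, such as SOX21-AS1 and PRKCH-AS1, both named after their values were seen, are uncertain.

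**Figure D3:**
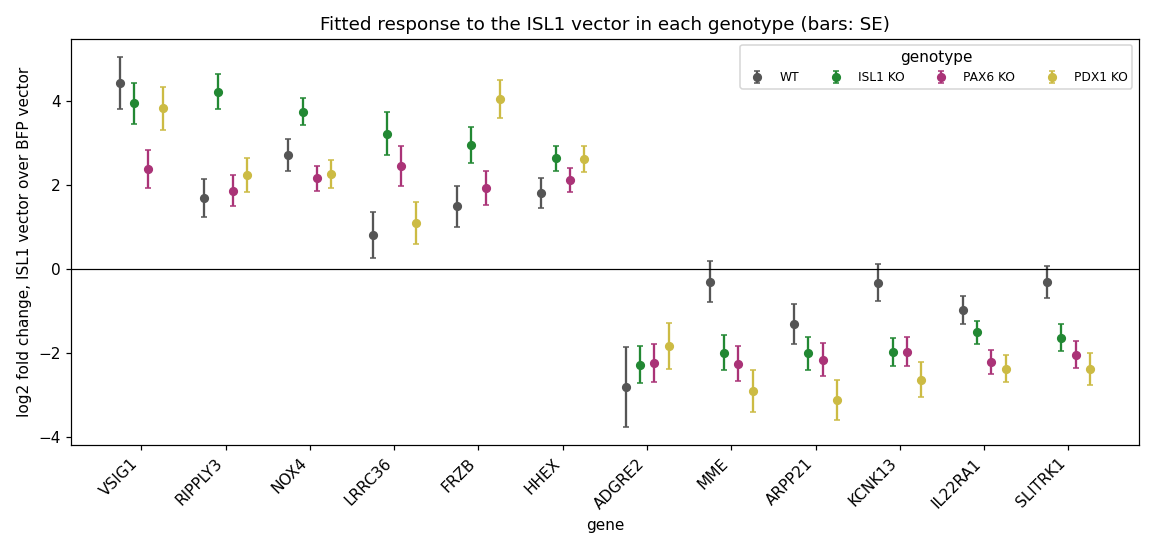
Fitted log2 fold change of libraries labelled ISL1 OE over BFP in WT, ISL1 KO, PAX6 KO and PDX1 KO for 12 genes called in both ISL1 KO and PAX6 KO without the replicate block. Points are edgeR estimates and bars ± SE derived from its F statistic. LRRC36, ADGRE2, KCNK13, IL22RA1 and SLITRK1 were picked after their values were seen; NOX4, for example, lies at 2.72 in WT, 3.75 in ISL1 KO and 2.16 in PAX6 KO.

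Comparing ISL1 KO ISL1 OE (n = 3) with WT BFP (n = 2) shows how far the knockout stayed from wild type after the vector. GCG (−3.67 ± 0.94, adjusted p = 0.0228), SST (−4.03 ± 0.87, adjusted p = 0.0092), IAPP (−3.66 ± 0.90, adjusted p = 0.0189) and ISL1 itself (−2.40 ± 0.38, adjusted p = 0.00133) remained lower than in WT. TPH1 (0.65 ± 0.53, adjusted p = 0.509), FEV (0.31 ± 0.41, adjusted p = 0.719) and NKX6-1 (0.65 ± 0.38, adjusted p = 0.324) did not differ by the test with all libraries. NKX6-1 was called higher in the reduced set (0.66 ± 0.24, adjusted p = 0.046), where TPH1 had adjusted p = 0.0802. PRDM14 (4.30 ± 0.76, adjusted p = 0.00264) and VSIG1 (4.21 ± 0.59, adjusted p = 0.000591) were higher than in WT, and TF (−5.56 ± 0.31, adjusted p = 4.79e-08) and AREG, the amphiregulin gene (−6.48 ± 1.22, adjusted p = 0.00414), were lower.

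None of 12 enterochromaffin-like genes passed (camera adjusted p = 0.633). Of 20 alpha cell genes 10 were lower, with 12 lower and 1 higher over the list alone (camera adjusted p = 1.55e-08). Of 12 delta cell genes 3 were lower and FRZB (1.55 ± 0.46) was higher, 5 and 1 over the list alone (camera adjusted p = 0.0284, or adjusted p = 0.0732 with an estimated correlation). Gamma and epsilon cell (5 of 11), acinar (4 of 13), liver (7 of 17), ER stress (5 of 16) and p53 response genes (3 of 14) were lower, 7, 7, 11, 7 and 7 over the list alone, with camera adjusted p = 8.15e-06, 0.000857, 6.43e-14, 3.45e-05 and 0.000147. Of 20 proliferation genes 5 were higher, among them CENPF (1.97 ± 0.40), and 17 over the list alone (camera adjusted p = 1.08e-09, or adjusted p = 0.139 with an estimated correlation). Islet hormone (5 of 7 lower), beta cell (7 of 28 lower, 1 higher) and secretory machinery genes (5 of 27 lower) had camera adjusted p = 1.95e-05, 0.000613 and 0.01, or adjusted p = 0.139, 0.122 and 0.491 with an estimated correlation, and 5, 9 and 6 were lower over the list alone. In all 617 genes were higher and 1176 lower, or 844 and 685 with library size alone, which moved the higher share from 34.4% to 55.2%. The reduced set had 3546 higher and 4153 lower, all 1793 included. The 1793 calls became 600 and 365 without WT BFP replicates 1 and 3, and 963, 922 and 856 without ISL1 KO ISL1 OE replicates 1, 2 and 3. GCG and IAPP lost the call each time, with adjusted p up to 0.141 and 0.0967, and SST lost it without WT BFP replicate 3 (adjusted p = 0.0754). FRZB lost the call with the replicate block within ISL1 KO and within PAX6 KO (adjusted p = 0.0684) and without each library except WT BFP replicate 1 (adjusted p up to 0.395), without which it had 2.44.

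The question of how many knockout changes the vector turned back was answered by counting genes called in a knockout against WT and called in the opposite direction by the vector in that knockout. In ISL1 KO these were 55 of 1449 genes, 3.80% (exact 95% interval 2.87 to 4.91%). Of these 25 had been lowered and then rose, GCG and HHEX among them, and 30 had been raised and then fell, CBLN1, DDC and MME among them. None moved in the same direction. In PAX6 KO they were 31 of 1476, 2.10% (1.43 to 2.97%), 13 lowered and then raised and 18 raised and then lowered, with 8 moving in the same direction. In PDX1 KO they were 1327 of 2529, 52.5% (50.5 to 54.4%), a share that came from the library labelled PDX1 KO ISL1 OE replicate 4, since it was 9.99% without it and 70.3% without replicate 2. The intervals cover counting error only. The knockout BFP libraries enter both comparisons, and 20 simulated sets, in which the BFP libraries were drawn again and the ISL1 OE libraries drawn with no vector effect, gave 0.05 such genes on average in ISL1 KO, at most 1, and 0 in PAX6 KO and PDX1 KO; lists independent of each other would share 3.24, 3.04 and 192. The covariance of the log2 fold changes was −0.190 in ISL1 KO, −0.119 in PAX6 KO and −0.905 in PDX1 KO, against −0.144, −0.143 and −0.144 in the simulations. The differences were −0.0460, 0.0239 and −0.761, so in PAX6 KO the covariance was no further below 0 than in the simulations. These drew every library independently, whereas libraries of the same number deviated together in ISL1 KO and PAX6 KO. The simulated values leave this out, so in these genotypes the comparisons of signs and of covariances do not decide whether changes were turned back. With 3 libraries a split of a BFP group would leave 1 on a side, so the controls were not split, and part of the excess over the independent overlap may come from them. In the reduced set the shares were 9.26%, 7.44% and 20.04%, and without WT BFP replicates 1 and 3 the ISL1 KO share was 7.56% and 8.05%. It was 2.35% and 2.16% without ISL1 KO BFP replicates 2 and 3, and 2.09%, 1.83% and 2.3% without ISL1 KO ISL1 OE replicates 1, 2 and 3. The PAX6 KO share was 4.33% and 3.82% without WT BFP replicates 1 and 3, 0.743% and 1.04% without PAX6 KO BFP replicates 1 and 3, and 0.796% and 1.3% without PAX6 KO ISL1 OE replicates 1 and 3. With the replicate block it was 0.748%, 11 of 1471 genes.

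Whether the vector effect differed between genotypes was tested directly. The effect in ISL1 KO minus that in WT called 1 gene, SLC24A4, a sodium, potassium and calcium exchanger gene named after its values were seen, and the effect in PAX6 KO minus that in ISL1 KO called the same gene in the other direction. The first call ended without each WT library, without ISL1 KO BFP replicates 1 and 3 and without ISL1 KO ISL1 OE replicates 1 and 3, where 0 genes were called, and the second without ISL1 KO BFP replicate 3. For PAX6 KO minus WT edgeR called 0 genes, with 750 at an unadjusted p under 0.05, while DESeq2 called 10 and limma-voom 0. GCG, called in ISL1 KO and not in WT or PAX6 KO, was not shown to differ with all libraries (ISL1 KO minus WT 5.78 ± 1.39, adjusted p = 0.678; PAX6 KO minus ISL1 KO −3.66 ± 1.18, adjusted p = 0.985). Both differences were called in the reduced set, at 5.78 ± 0.68 (adjusted p = 0.00137) and −5.76 ± 0.67 (adjusted p = 0.00152). The delta cell list responded less in PAX6 KO than in ISL1 KO (camera adjusted p = 0.000137), with no member passing over all genes and 1 lower over the list alone. For PDX1 KO minus WT 263 genes were higher and 40 lower, together 1.37% of the 22184 genes tested, led by the bile acid transporter subunit gene SLC51B (6.38 ± 1.49), GAST (6.35 ± 1.43) and FABP1, a fatty acid binding protein gene (5.99 ± 1.12). In the reduced set these differences were 0.39 ± 0.72, 0.86 ± 0.48 and 2.36 ± 0.48, with adjusted p = 0.858, 0.427 and 0.0114. For PDX1 KO minus ISL1 KO 0.523% of the genes tested were called, with 5 genes lower and the rest higher. Both counts moved with each library labelled PDX1 KO ISL1 OE. Without replicate 4, 135 genes were called against WT (0.582%), 22 of them lower and the rest higher, and 68 higher and 4 lower against ISL1 KO (0.310%). Without replicate 2 the shares were 35.6% in both, with 3733 higher and 4535 lower against WT and 3735 higher and 4516 lower against ISL1 KO. With the replicate block within ISL1 KO and within PAX6 KO the shares were 0.762% and 0.284%, and SLC51B, GAST and FABP1 lost the call against WT (adjusted p = 0.0972, 0.0860 and 0.0501). With only the compared groups in the fit edgeR called 0 genes for PDX1 KO minus WT, with 2461 at an unadjusted p under 0.05, while over all libraries DESeq2 called 3.63% and limma-voom 0.568%. The count for PDX1 KO minus WT was 83 and 104 without WT BFP replicates 1 and 3, 12 and 33 without WT ISL1 OE replicates 1 and 2, and 174, 123 and 129 without PDX1 KO BFP replicates 1, 2 and 3. The share for PDX1 KO minus ISL1 KO was 0.190% and 0.235% without ISL1 KO BFP replicates 1 and 2, 0.239%, 0.230% and 0.163% without ISL1 KO ISL1 OE replicates 1, 2 and 3, and 0.198%, 0.212% and 0.221% without PDX1 KO BFP replicates 1, 2 and 3. Acinar genes responded more in PDX1 KO than in ISL1 KO (1 of 13 higher, 7 over the list alone; camera adjusted p = 5.63e-05).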

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

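The tests of explanations given here were chosen after the results were seen, except the counts of other splits of the libraries, which were set before.

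ISL1 RNA was not detectably higher in libraries labelled ISL1 OE than in BFP libraries. Too few reads to see a rise is argued against by the upper 95% bound of the log2 fold change in ISL1 KO, 0.78, at 61.6 to 84.0 CPM of ISL1 in the libraries labelled ISL1 OE. In ISL1 KO and PAX6 KO the lower bounds of −0.56 and −0.52 leave no 2-fold rise in the libraries labelled BFP. The upper bounds of 0.78 and 0.82 leave none in those labelled ISL1 OE either. ISL1 RNA therefore cannot tell whether vector labels were exchanged there. GCG and HHEX, lower in ISL1 KO than in WT, rose in ISL1 KO ISL1 OE, toward WT. In WT the bound of −1.09 alone decides nothing. An exchange in WT alone is argued against by the 39 genes called in both of these genotypes, 35 of which had the same sign in WT. NOX4 and RARRES2, called higher in WT as in both, argue against it too. Transgene reads that were not counted to the ISL1 gene also stay open: the shorter coding ISL1 transcript, ENST00000511384 with 978 coding bases, had an estimated count of at most 1.54 in ISL1 KO ISL1 OE, but the vector's coding sequence is not given in the sources used here. That the vector raised ISL1 before day 18 and was then silenced was not tested.

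GCG rose in ISL1 KO given the ISL1 vector, to 7.65% of its distance to WT on average. WT cells mixed into these libraries are argued against: of 27 other genes at least 16-fold lower in ISL1 KO than in WT, 19 stayed below the level that share would need in every ISL1 OE library, with a median regained of 1.07% over the genes, GCG included. The lane set of the run is argued against by a log2 fold change of GCG of 5.38 among the libraries of lanes 1 to 4. A response of ISL1 KO cells to the vector therefore stays open as a hypothesis, with the ISL1 RNA level not raised.

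The library labelled PDX1 KO ISL1 OE replicate 4 differed from its partner. Cells of another line than the PDX1 knockout are a candidate explanation: of 13 genes found in all 4 WT libraries and low in 14 knockout libraries, chosen without this library, its partner and PAX6 KO ISL1 OE replicate 3, 12 lay above all 14 here, LINC02864 with 21.5 CPM against at most 0.0928 in the 14 and 15.4 to 21.6 in WT; A2M, at 18.9 against 24.6, was the exception. In the partner library 4 of the 13 did so, and in PAX6 KO ISL1 OE replicate 3 1 did. Transcript length bias, seen in both libraries as a rank correlation of −0.464 and −0.499 between deviation and exon length, is argued against as the whole cause, since the median difference of the 13 genes from the partner was 4.12 after the trend was removed and 3.94 before. A response to ISL1 in the PDX1 knockout would raise these genes in the partner too, where 0 of the 13 lay 4-fold above every PDX1 KO BFP library, but it cannot be told apart from a wrong label with 1 library on each side.

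The vector effect was tested for differences between genotypes, and these results stood out. In ISL1 KO against WT 1 gene differed, SLC24A4. In PAX6 KO against ISL1 KO the same gene was the only 1. In PDX1 KO against WT 1.37% of the genes tested differed, 303 genes, and in PDX1 KO against ISL1 KO 0.523%, among them INS with a log2 difference of 6.27, all with the library labelled PDX1 KO ISL1 OE replicate 4 in the fit; INS had 0.16 ± 0.40 (adjusted p = 0.968) in the reduced set and adjusted p = 0.130 with the replicate block within genotypes.

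Other splits of the same libraries were counted. In ISL1 KO the real split called 94 genes and was the 1 of 10 splits to call as many, the highest other calling 0; in PAX6 KO it called 92, and 2 of 10 splits called as many, the highest other calling 266. These 10 splits are too few for a share under 0.05. The split of 266 set PAX6 KO BFP replicate 2 and PAX6 KO ISL1 OE replicates 1 and 2 against the rest and so kept numbers 2 and 3 whole on opposite sides. Libraries of these numbers correlate in their deviations with r = 0.512 and 0.546, a structure of the samples that the replicate block takes out; with it the real comparison called 35 genes. Among the 4 splits that part all 3 pairs, the 3 others called 0 genes in either genotype, while the splits that keep a pair together differ from these in holding the pair's shared deviation. For the difference between PAX6 KO and ISL1 KO 7 of 40 splits called as many genes, at most 4, so chance is not excluded.

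A shared response to the vector in different genotypes is a hypothesis for the 39 genes called in the same direction in ISL1 KO and PAX6 KO, which share no library; 0 were called in opposite directions. With the replicate block 19 genes were called in both, 17 of them among the 39.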

How the results depend on the processing

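The lane set as a covariate, the libraries of lanes 1 to 4 only, the replicate block within ISL1 KO and PAX6 KO, and the reduced set without the 2 libraries that stand apart were chosen after the data were seen; the other alternatives were planned. The planned use of a table of counts without gene names as an alternative was not run. Of 556 values of genes named by rule, 552 kept their direction and their side of the threshold with RLE factors, 556 with the rounded count table, 546 with a minimum of 10 counts in 2 libraries, 544 with DESeq2, 542 with the robust spread and 529 with no filter. With the lane set as a covariate 504 kept them, with limma-voom 495, with library size alone 474, and with limma on log2(TPM + 1) 389. With only the compared groups in the fit 398 of 555 did. Among libraries of lanes 1 to 4 only, 101 did and 455 lost the call in the same direction; WT BFP, ISL1 KO BFP, PAX6 KO BFP, PAX6 KO ISL1 OE and PDX1 KO BFP each had 1 library fewer there. The causes of the differences that follow were not tested except where fewer libraries or genes entered a fit.

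Counts of called genes are given in the order of the vector comparisons in WT, ISL1 KO, PAX6 KO and PDX1 KO (8, 94, 92 and 3200), then ISL1 KO, PAX6 KO and PDX1 KO against WT (1449, 1476 and 2529). For ISL1 KO ISL1 OE against WT BFP and the 2 differences with PDX1 KO the percent of genes tested in each fit is given instead (8.08% for the first). DESeq2 called 63, 388, 499 and 5038, then 2556, 2574 and 3664, and 9.40% of 33407 genes tested. With only the compared groups in the fit the counts were 281, 1461, 0 and 0, then 5752, 4903 and 6632, and 37.7%. Among libraries of lanes 1 to 4 only they were 0, 4, 0 and 189, then 75, 27 and 47, and 0.513%. In the reduced set they were 388, 1361, 1384 and 2570, then 6541, 6613 and 7655, and 33.5%. With library size alone the counts in ISL1 KO, PAX6 KO and PDX1 KO were 73, 55 and 2110, that of PAX6 KO against WT was 1256 and the share of ISL1 KO ISL1 OE against WT BFP 6.89%. No filter gave 13 in WT, and limma-voom gave 2529 in PDX1 KO.

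For the differences between vector effects, ISL1 KO minus WT (1 gene) gave 0 with library size alone, 26 with DESeq2, 99 with only the compared groups, 2 with the block within genotypes, 0 with lanes 1 to 4 and 72 in the reduced set. PAX6 KO minus WT (0 genes) gave 10 with DESeq2 and 13 in the reduced set. PDX1 KO minus WT (1.37%) gave 0.771% with library size alone, 3.63% with DESeq2, 0.568% with limma-voom, 0 with only the compared groups (2461 genes at an unadjusted p under 0.05), 0.762% with the block within genotypes, 0.987% with the lane set, 0.00863% with lanes 1 to 4 and 3.28% in the reduced set. PAX6 KO minus ISL1 KO (1 gene) gave 3 with DESeq2, 0 with lanes 1 to 4 and 5 in the reduced set. PDX1 KO minus ISL1 KO (0.523%) gave 0.293%, 1.68%, 0.216%, 0.140%, 0.284%, 0.347%, 0 and 1.30% under library size alone, DESeq2, limma-voom, only the compared groups, the block within genotypes, the lane set, lanes 1 to 4 and the reduced set.

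Numbers pair libraries within ISL1 KO and PAX6 KO. The replicate block there gave 35 calls for the vector in PAX6 KO and, for the vector in ISL1 KO, 78, of which 61 were shared with the 94. In the other comparisons the block changed 48 of 504 named values, 47 losing the call and 1 gaining it, among them TPH1, LMX1A and SLC18A1 in ISL1 KO against WT. Of 312 list tests it changed 5: mitochondrially encoded genes in PAX6 KO against WT (adjusted p = 0.0589) and in PAX6 KO minus WT (0.0529), beta cell genes in PAX6 KO minus WT (0.0529) and enterochromaffin-like genes in PDX1 KO minus ISL1 KO (0.0595) lost the call, and mesenchyme genes in ISL1 KO ISL1 OE against WT BFP (0.0356) gained it. Elsewhere only 1 or 2 numbers were shared, too few to decide pairing. Deviations there correlated at −0.0109 for number 1 in WT and −0.405 for number 2 in PDX1 KO. Against WT BFP, ISL1 KO had 0.151 and 0.270, PAX6 KO −0.287 and 0.396, PDX1 KO 0.505 and 0.205, and ISL1 KO ISL1 OE 0.229 and 0.244. The replicate block over all groups gave 39, 478, 662 and 566 calls for the vector in the 4 genotypes, 3164, 3443 and 4586 against WT, 16.97% for ISL1 KO ISL1 OE against WT BFP, 0.708% and 0.194% for PDX1 KO minus WT and minus ISL1 KO, and 2 genes for PAX6 KO minus ISL1 KO.

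Leaving out each library in turn gave 0 to 5 calls for the vector in WT, 20 to 54 in ISL1 KO, 17 to 129 in PAX6 KO and 718 to 10860 in PDX1 KO. Against WT it gave 450 to 935 calls for ISL1 KO, 277 to 1024 for PAX6 KO, 771 to 1785 for PDX1 KO and 1.57% to 4.35% for ISL1 KO ISL1 OE. For the differences it gave 0 to 2 (ISL1 KO minus WT), 0 to 0 (PAX6 KO minus WT), 0.0516% to 35.6% (PDX1 KO minus WT), 0 to 2 (PAX6 KO minus ISL1 KO) and 0.163% to 35.6% (PDX1 KO minus ISL1 KO). The share turned back ran from 1.83% to 8.05% in ISL1 KO, 0.743% to 4.33% in PAX6 KO and 9.99% to 70.3% in PDX1 KO. A group left with 1 library was assumed to vary like the other groups. The share was 9.26% in ISL1 KO and 7.44% in PAX6 KO in the reduced set, 20.04% there and 38.8% at the stricter threshold in PDX1 KO, and 0.748% and 49.4% in PAX6 KO and PDX1 KO with the replicate block within genotypes.

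With an estimated correlation 108 of the 312 list tests lost their call and 0 gained one. The lists called were then 3, 3, 1 and 3 for the vector in WT, ISL1 KO, PAX6 KO and PDX1 KO (11, 10, 11 and 12 at the preset correlation), 9, 8, 4 and 6 against WT (12, 15, 16 and 11), and 0, 0, 0, 1 and 1 for the differences (12, 9, 13, 6 and 9). On log2(TPM + 1) 283 list tests kept their direction and their side of the threshold, and in the reduced set 267, with 11 lists called for PAX6 KO minus ISL1 KO.

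Directions turned in the reduced set to lower for islet hormone genes with the vector in PAX6 KO (adjusted p = 0.921) and in PDX1 KO minus ISL1 KO (0.000197), for beta cell genes in PDX1 KO minus ISL1 KO (0.042), for neuron genes in PAX6 KO minus ISL1 KO (0.0435), and for mitochondrially encoded genes with the vector in PAX6 KO (0.573) and PDX1 KO (0.328), in PAX6 KO minus WT (0.913), PDX1 KO minus WT (0.49) and PDX1 KO minus ISL1 KO (0.57). With the vector in PDX1 KO, PRDM14 turned to −0.39 without replicate 2 of the libraries labelled ISL1 OE, against 3.41 without replicate 4. PHLDA3 turned to −0.064 with the replicate block, −0.056 in the reduced set and −0.048 without replicate 4, against 2.37 without replicate 2, and LDHA to −0.62, −0.48 and −0.47, against 2.24.

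Against TMM, library size alone moved the median log2 fold change of all genes by 0.10 for the vector in WT and −0.17 in PDX1 KO, by 0.18, 0.23 and 0.11 for ISL1 KO, PAX6 KO and PDX1 KO against WT, by 0.23 for ISL1 KO ISL1 OE against WT BFP, and by −0.11, −0.27 and −0.22 for PAX6 KO minus WT, PDX1 KO minus WT and PDX1 KO minus ISL1 KO. Every library held at least 40959445 counts; counts were not thinned, so how far depth, the number of libraries or their spread limits the calls was not compared.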

Other observations

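Among liver genes, 7, 11 and 13 of 17 were lower than in WT BFP in ISL1 KO, PAX6 KO and PDX1 KO, and the call of the list in PDX1 KO was lost with an estimated correlation (adjusted p = 0.0615). These comparisons use the same 2 WT BFP libraries, so they are not independent of each other, and against those libraries camera called the list lower in WT ISL1 OE too (adjusted p = 2.61e-06, or adjusted p = 0.226 with an estimated correlation). Examples were vitronectin, VTN, at −2.26 ± 0.38, −1.49 ± 0.38 and −2.25 ± 0.38, and albumin, ALB, at −1.95 ± 0.43, −2.52 ± 0.44 and −3.06 ± 0.44, the most abundant plasma protein. Of 20 proliferation genes 6 fell in PDX1 KO, among them the mitotic kinase gene CDK1 (−1.15 ± 0.31) and NUSAP1 (−1.21 ± 0.29), a spindle protein gene, and 5 were higher in ISL1 KO ISL1 OE than in WT BFP, among them the replication licensing gene MCM5 (1.54 ± 0.34) and E2F1 (1.43 ± 0.38). In neither case did the list's call hold with an estimated correlation (adjusted p = 0.237 and 0.139). In the reduced set 15 fell and 19 rose.

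CDKN1A, the cell cycle inhibitor induced by p53, fell in ISL1 KO (−1.91 ± 0.27) and PAX6 KO (−1.44 ± 0.27), and HSPA5, the ER chaperone BiP, had −0.74 ± 0.15, −0.83 ± 0.15 and −1.03 ± 0.15 in ISL1 KO, PAX6 KO and PDX1 KO. The same WT BFP libraries enter each of these, and the ER stress list was also called lower in WT ISL1 OE against them (camera adjusted p = 0.00803, or adjusted p = 0.127 with an estimated correlation). Of 18 interferon response genes 4 rose and 1 fell in ISL1 KO, with adjusted p = 0.15 for the list with an estimated correlation; OAS1 (1.52 ± 0.23) and IRF7 (1.13 ± 0.21) rose there, and in PAX6 KO IFIH1 (−1.54 ± 0.20) and IFIT3 (−1.59 ± 0.36) fell. Whether these lists differ between knockouts was not tested.

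In PAX6 KO ISL1 OE the ghrelin gene GHRL had 6373 ± 7208 CPM, with 14691 CPM in replicate 3, and in the reduced set its log2 fold change against PAX6 KO BFP was −0.52 (adjusted p = 0.191). The deviations of PAX6 KO ISL1 OE replicate 3 and of the library labelled PDX1 KO ISL1 OE replicate 4 from their partners correlated with r = 0.703 over 15244 genes, which are not independent replicates. Among the shortest of 3 equal groups of genes by exon length the median deviations were 0.77 and 0.82, and among the longest −0.81 and −0.96, on the log2 scale.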
